A study of Mus with 8 samples.

How the data were processed

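Subcutaneous tumours were profiled that had grown from MC38 cells, a mouse colon cancer line, in 4 wild-type hosts (WT host) and in 4 hosts with floxed Ext1 and an S100a4-driven Cre (Ext1S100a4Cre host). Per the labels, tumours were taken 25 to 30 days after transplantation, total RNA came from the whole tumour, and 0.5 µg of it was amplified and labelled with Cy3 for a 1-colour Agilent array. Tumour cells, fibroblasts, immune cells and other host cells were therefore measured together. Each array had 62976 spots, of which 3671 were controls, and held 56605 probes, 300 of them with 10 spots each. The 8 arrays lay on 1 slide, in 2 slide rows that each held 2 tumours of either host.

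Per the file headers, the deposited scanner files came from Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name version 9.1. The deposited values are spot intensities on a linear scale: per the file headers, the processed intensity of a spot had its background subtracted and detrended, and the median intensities of spot and surroundings were given beside it. The other deposited columns that were used hold flags of 0 or 1, which mark spots well above background, saturated spots and 2 kinds of outlier. The deposited series matrix holds the same processed intensities: 99.242% to 99.272% of its values per array equalled the scanner files' within 0.01%, and the median ratio was 1 on each array. It therefore carries no scaling between arrays and no centring.

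From the scanner files, log2 of the processed intensity was taken and the array's 75th percentile over all probes that are not controls was subtracted. Control spots were left out, and a spot with an outlier flag was left out on its array (53 to 132 spots per array, with 48 probes lacking a value on at least 1 array). No spot was saturated. Spots of the same probe were averaged. Probes well above background on at least 4 of the 8 arrays, whatever their group, were kept (39716). Probes were named through their accession, without versions, in a RefSeq gene table of assembly GRCm38.p6. This gave a symbol to 32994 probes (22911 genes) and none to 23611, which kept the file's own identifier. The headers name mouse build mm9, so the table served only for names, chromosomes and gene order. Each gene, or each unnamed transcript, was represented by its kept probe with the highest mean over the 8 arrays. This left 31281 genes and transcripts to test (17240 named, 14041 not), and the word genes covers both in the counts. Brightness over background and the number of arrays limit the precision.

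The hosts were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, with no covariates), with Benjamini-Hochberg adjustment over all 31281 genes and a threshold of 0.05. Differences are log2 values of the Ext1S100a4Cre host minus the WT host, and errors are limma's standard errors (SE) or the standard deviation (SD) between tumours. Where a probe was not well above background on any array of a group, the fold is a lower bound, computed against the lowest signal well above background on each array of that group. Values for single genes and list means were also compared with an exact two-sided permutation test over the 70 ways to assign 4 of 8 tumours, whose smallest possible p is 0.0286. Separation of the groups was tested by the between-group minus within-group distance over the 35 distinct splits (exact, one-sided). 36 gene lists, 8 of them primary and 28 secondary, were tested with limma's fry, which asks whether a list's genes move on balance in 1 direction, with adjustment over the 36 lists. Adjusted p values given for lists are fry's. A list's members were also adjusted over the list alone. Files were read with the packages jsonlite 2.0.0 and data.table (version 1.17.8).

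The groups, tests, filter, gene lists and the rule for naming genes were fixed before the data were examined. By that rule Ext1 and S100a4 are always named. In each direction up to 12 genes are named, first those past the adjusted threshold with no overlap between the groups, by size of difference. Remaining places go, by smallest unadjusted p, to genes with unadjusted p under 0.05, at least a 2-fold difference and no overlap, which are said to have missed the threshold. Unnamed transcripts and genes known only by a clone, model or accession name are counted and not named. For each list up to 4 members with the smallest unadjusted p serve as examples, and any member of the heparan sulfate list may be named. The other alternatives were normexp background correction, quantile and median scaling, the series matrix, no filter, a filter requiring all 8 arrays, the mean of a gene's probes, every probe on its own, the replicate number or the slide row as a block, array weights, a trended and robust variance, a threshold of 0.1, camera in place of fry, and leaving out each tumour. The files hold no mean spot intensity, so normexp (offset 50) used the median spot and background intensities. A pair of alternatives that leave out 2 Ext1S100a4Cre host tumours each was added after seeing the data.

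The gene and list tests were tested on simulated data with each gene's mean and residual spread on these arrays, and for lists also the correlation of the residuals between genes. With 200 of 31233 genes changed in each of 20 draws, limma recovered 34% of 2-fold, 73.7% of 4-fold and 86.5% of 8-fold differences between the hosts, with 4.93% false calls. With a shift of 1 log2 unit given to 1 list at a time in 100 draws, fry called the heparan sulfate list in 100% of draws, the cell cycle list in 23% and the endothelium list in 21%. It called the collagen list in 7%, the fibroblast list in 5%, the T and NK cell and macrophage lists in 4% each and the interferon list in 1%, so a 2-fold shift of these lists would mostly be missed. With no shift, 4% of draws had any list called.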

Results

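Gene expression was measured in whole subcutaneous tumours of MC38 cells, 4 from WT hosts and 4 from Ext1S100a4Cre hosts. Ext1 encodes a polymerase that elongates heparan sulfate, the sulfated sugar chain of cell-surface and matrix proteoglycans. S100a4 is active in fibroblasts and in some immune cells, so the deletion was directed at host cells and left Ext1 of the transplanted MC38 cells intact. The question was how tumours differ when such host cells lack Ext1. The 75th percentile of intensity ran from 846.9 to 1265 across the 8 arrays. Tumours 1 and 4 of the Ext1S100a4Cre host had the lowest values (854.8 and 846.9). On their arrays 65.65% and 65.96% of probes were well above background, against 68.83% to 71.09% on the other 6.

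Ext1 mRNA in the whole tumours was 0.28 log2 units lower in the Ext1S100a4Cre host, less than the spread between tumours could separate from none. Its level, relative to the array's 75th percentile, was -0.18 ± 0.33 (SD, n = 4) in the WT host and -0.46 ± 0.15 (SD, n = 4) in the Ext1S100a4Cre host. Single WT host tumours measured -0.55, -0.28, 0.24 and -0.15, and Ext1S100a4Cre host tumours -0.62, -0.27, -0.54 and -0.42. The difference of -0.28 (SE 0.18) had an adjusted p of 0.747 in limma and an exact permutation p of 0.229. Its 95% interval ran from -0.70 to 0.15, so a loss to 0.614 of the WT level was not excluded. The files do not say whether the Ext1 probe lies in the deleted part, so its value does not check the genotype. S100a4 was abundant in both groups, at 3.71 ± 1.14 and 3.82 ± 0.90 (SD, n = 4 each), with a difference of 0.11 (SE 0.63, adjusted p = 0.968) that became -0.14 with the unscaled series matrix.

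**Figure D1:**
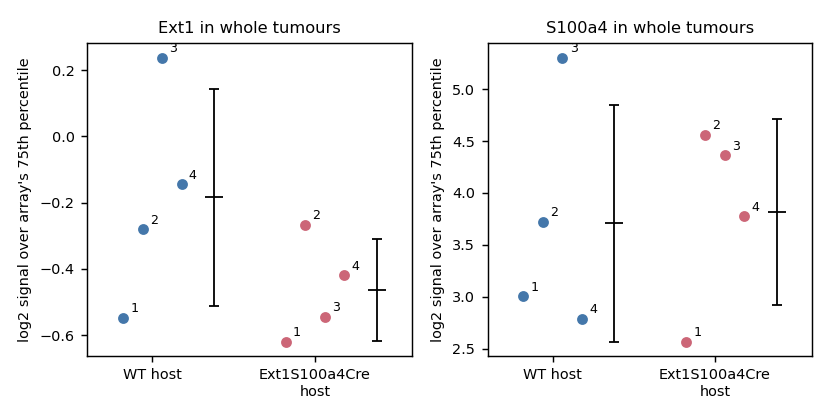
Level of Ext1 and S100a4 in each tumour, as log2 signal over the array's 75th percentile; points are tumours with their replicate number, and the black mark and bar give mean and SD of 4. The groups overlap for both genes, with Ext1 means of -0.18 and -0.46.

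In the tumours of the Ext1S100a4Cre host the B-cell genes Ms4a1, Cd79b and Fcmr were lower and the muscle gene Actn3 higher in a test adjusted over their own list, and no gene passed over all genes. No gene list passed its test. List means were lower for macrophages, fibroblasts and collagens and higher for erythrocytes and for skeletal muscle, with the muscle signal in tumours 2 and 3. Limma called 0 of 31281 genes at an adjusted p of 0.05 and 0 at 0.1. At unadjusted p under 0.05 there were 2050 genes, 6.55% of those tested, with 1374 higher and 676 lower in the Ext1S100a4Cre host. Of these, 462 differed at least 2-fold, 205 higher and 257 lower. The 2 groups did not overlap for 1413 genes (4.52%, against 2.86% by chance). The groups as a whole were not separated (exact permutation p = 0.257, one-sided, 35 splits). The first principal component held 49.8% of the variance and ran from Ext1S100a4Cre host tumour 1 (-122) to WT host tumour 3 (133.3).

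Among genes higher in the Ext1S100a4Cre host without overlap, 3 encode parts of the muscle sarcomere and its attachments. Actn3 (actinin alpha 3) was higher by 3.04 log2 units (SE 0.66), Mypn (myopalladin) by 2.85 (SE 0.57) and Nrap by 1.98 (SE 0.37). Mypn was well above background in only 2 of 4 WT host tumours, so its difference rests partly on background readings. Cdh2, which encodes N-cadherin, was 2.43-fold higher, and Hey1, a target of Notch signalling, 3.24-fold higher. Col13a1, a collagen that spans the cell membrane, was 2.05-fold higher. The differences of Klhl30, Ttll9, Pla2g3, Rflna and Slc24a2 were 1.98, 1.98, 1.75, 1.30 and 1.11. Atp6v0e2, a subunit of the vacuolar proton pump, was higher by 1.10 and lies on chromosome 6, whose genes as a set had a median difference of 0.116. All 12 missed the threshold, with limma's adjusted p between 0.429 and 0.694. The exact permutation p of each was 0.0286, which the choice of genes without overlap fixes, so it adds no support.

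Among genes lower in the Ext1S100a4Cre host without overlap, 3 are B-cell surface genes. Ms4a1, the gene of CD20, was at least 5.03-fold lower, Fcrl1 at least 1.71-fold lower, and Fcmr, the receptor for IgM, 2.54-fold lower. Klrh1, a lectin-like receptor gene on chromosome 6, was at least 1.66-fold lower. Ms4a1, Fcrl1 and Klrh1 were well above background in 4 of 4 WT host tumours and in 0 of 4 Ext1S100a4Cre host tumours. Their bounds were computed in the report's processing only. Over 20 alternatives the log2 differences of these 3 genes shrank to as little as -0.705, -0.166 and -0.216. Chga, the secretory granule protein chromogranin A, was lower with a difference of -2.87 (SE 0.55), Car12, a carbonic anhydrase, with -2.42 (SE 0.56), and Fgg, the fibrinogen gamma chain, with -2.27 (SE 0.43). Ly6k and the tetraspanin Tspan8 differed by -1.93 and -1.34. The differences of Lhx8, Zscan5b and Trim42 were -1.11, -1.03 and -1.02, but a second Lhx8 probe, well above background on all 8 arrays, gave 0.025, and Trim42 turned to 0.052 with normexp. All 12 missed the threshold, with limma's adjusted p between 0.429 and 0.733. Here too the choice of genes without overlap fixes the exact permutation p at 0.0286.

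Of the B-cell list, 3 genes passed a test adjusted over the list, while Sdc1 and Xbp1 also stand in other lists. Ms4a1, Fcmr and Cd79b (-1.50, SE 0.37), a chain of the B-cell receptor, were lower in all Ext1S100a4Cre host tumours than in any WT host tumour. Adjusted over the list alone, which had 14 measured members, their limma p values were 0.00594, 0.0162 and 0.0162, and over all genes 0 members passed. The whole list of B cells and plasma cells differed by -0.46 and did not pass (fry adjusted p = 0.637, for changes in either direction 0.126). In it 8 members had a lower and 6 a higher mean. The B-cell genes Pax5 (0.086), Cd22 (0.033) and Cd79a (0.078, well above background in 3 of 4 tumours of each host) were among the 6. Without WT host tumour 3, which stood at 1.22 relative to the mean of the 8 tumours, the list differed by -0.12. Of these 3 genes, 0 passed over the list alone with normexp, 2 without Ext1S100a4Cre host tumour 1, 0 without tumours 1 and 4, and 2 without tumours 2 and 3.

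**Figure D2:**
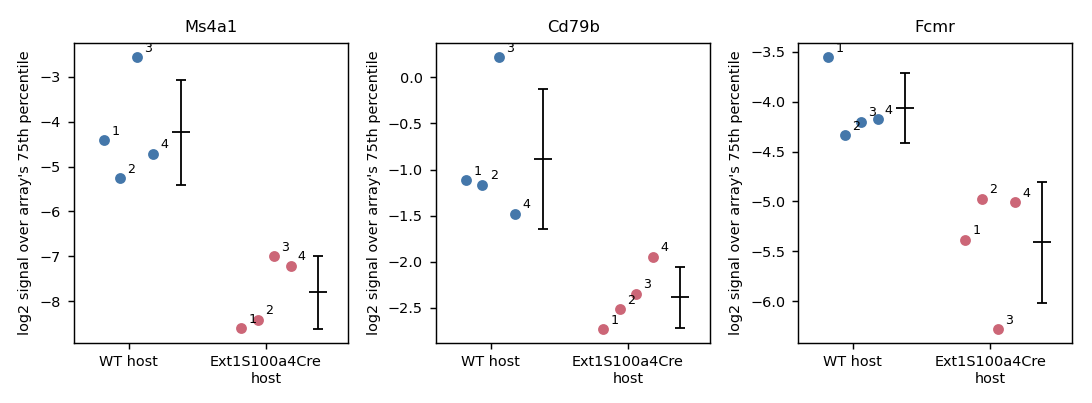
Level of the B-cell genes Ms4a1, Cd79b and Fcmr in each tumour, as log2 signal over the array's 75th percentile; points are tumours with their replicate number, and the black mark and bar give mean and SD of 4. For each gene the 4 Ext1S100a4Cre host tumours lie below the 4 WT host tumours; Ms4a1 was not well above background in the Ext1S100a4Cre host.

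Genes for making and modifying heparan sulfate differed little on average. Of 25 measured members, 10 had a higher and 15 a lower mean, and the list mean differed by -0.089 (fry adjusted p = 0.703, exact permutation p = 0.0857), or -0.04 without Ext1S100a4Cre host tumour 1, with the direction reversed under normexp. Hpse, which encodes the enzyme that cleaves heparan sulfate, had the smallest unadjusted p, with a difference of -0.97 (SE 0.36, adjusted p = 0.747). Xylt1, which starts the chain, differed by 0.28 and the sulfotransferase Hs6st2 by 0.57, neither past the threshold. The list mean was -0.46 ± 0.035 (SD, n = 4) in the WT host and -0.55 ± 0.095 (SD, n = 4) in the Ext1S100a4Cre host. Proteoglycan core proteins differed by -0.57 (20 of 26 members lower, adjusted p = 0.703) and chondroitin and hyaluronan synthesis by -0.30 (15 of 22 lower, adjusted p = 0.637). Growth factors that bind heparin had the smallest unadjusted fry p of all lists, 0.0513. Their mean differed by -0.60, 20 of 26 members were lower, Bmp2 differed by -1.15 (SE 0.46), and the adjusted p was 0.637. Without Ext1S100a4Cre host tumour 1 the list means differed by -0.36 for these growth factors, -0.12 for core proteins and -0.15 for chondroitin and hyaluronan synthesis, and without WT host tumour 3 by -0.45, -0.35 and -0.17.

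Fibroblast and matrix genes had lower means in the Ext1S100a4Cre host. In the fibroblast and collagen lists WT host tumour 3 was highest and Ext1S100a4Cre host tumour 1 lowest. The fibroblast list differed by -1.24 (23 of 25 members lower, adjusted p = 0.674) and the list of collagens and fibril assembly by -0.99 (35 of 36 lower, adjusted p = 0.637). Col1a1 and Col3a1, the main fibrillar collagens, differed by -1.80 (SE 0.71) and -2.11 (SE 0.88), Col6a3 by -1.34 (SE 0.51) and Col18a1, a heparan sulfate proteoglycan, by -0.55 (SE 0.21). These 4 collagens had unadjusted p under 0.05 and 0 passed over the list alone. Relative to the mean of the 8 tumours, the fibroblast list stood at 1.91 in WT host tumour 3 and at -2.73 in Ext1S100a4Cre host tumour 1. The other 6 tumours lay between -0.82 and 0.82. Without Ext1S100a4Cre host tumour 1 the fibroblast and collagen lists differed by -0.53 and -0.43, and without WT host tumour 3 by -0.80 and -0.79. Without Ext1S100a4Cre host tumours 1 and 4 they differed by -0.08 and -0.23. Matrix proteases and inhibitors differed by -0.96 (25 of 25 lower, Plau -1.35, adjusted p = 0.637), and TGF-beta response genes by -0.50 (18 of 21 lower, adjusted p = 0.637). Wnt target genes differed by -0.44 (12 of 22 lower, adjusted p = 0.854), with Sfrp2, well above background in 2 of 4 Ext1S100a4Cre host tumours, at -4.07 (SE 1.76). Without Ext1S100a4Cre host tumour 1 these 3 lists differed by -0.45, -0.16 and -0.20. Hedgehog target genes had a mean difference of -0.062 and a median of 0.072 (Gas1 -1.45, adjusted p = 0.854), and normexp reversed the direction of their test; without that tumour the mean was 0.09.

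**Figure D3:**
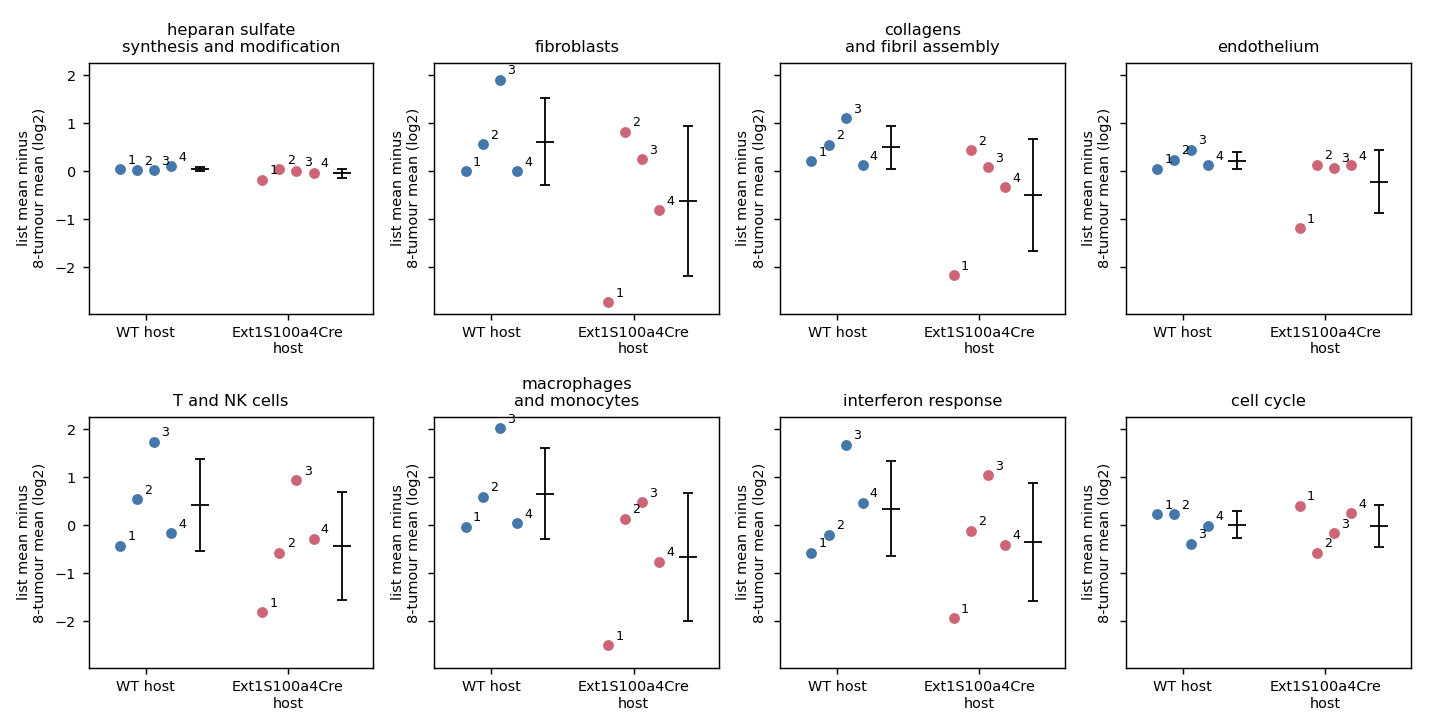
Mean of each primary gene list in each tumour, in log2 units relative to the mean of the 8 tumours; points are tumours with their replicate number, and the black mark and bar give mean and SD of 4. WT host tumour 3 lies highest and Ext1S100a4Cre host tumour 1 lowest for fibroblasts, collagens, endothelium, T and NK cells, macrophages and interferon response, and no list passed its test.

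Immune lists other than that of mast cells were also highest in WT host tumour 3 and lowest in Ext1S100a4Cre host tumour 1. Macrophage and monocyte genes differed by -1.32 (23 of 25 lower, adjusted p = 0.637), with 2.02 in WT host tumour 3 and -2.50 in Ext1S100a4Cre host tumour 1. Cx3cr1, a chemokine receptor of monocytes and macrophages, was 6.75-fold lower without overlap, Ms4a7 differed by -2.57 (SE 0.92), Adgre1, a macrophage surface gene, by -2.25 (SE 0.92) and the scavenger receptor Msr1 by -1.16 (SE 0.44). Of these 4, 0 passed over the list alone (smallest adjusted p 0.188). T and NK cell genes differed by -0.86 (23 of 25 lower, Cd3g -1.63, Cd5 -0.90, adjusted p = 0.694). MHC class I and II genes differed by -1.04 (23 of 23 lower, H2-Ob -0.74, adjusted p = 0.637) and interferon response genes by -0.70 (28 of 28 lower, Psmb8 -1.27, Psmb9 -1.06, adjusted p = 0.707). Without Ext1S100a4Cre host tumour 1 macrophages differed by -0.71, T and NK cells by -0.40, MHC by -0.72 and interferon response by -0.17. Without tumours 1 and 4 these list means differed by -0.35, -0.24, -0.59 and 0.12. Without WT host tumour 3 these 4 lists differed by -0.87, -0.42, -0.66 and -0.26. Dendritic cell genes differed by -0.60 (13 of 16 lower, adjusted p = 0.707), chemokines by -0.56 (20 of 25 lower, with Ccl24 at 2.99, SE 1.26; adjusted p = 0.703) and neutrophil genes by -0.50 (12 of 17 lower, adjusted p = 0.793). Without WT host tumour 3 these 3 lists differed by -0.23, 0.01 and 0.09, and without Ext1S100a4Cre host tumour 1 by -0.20, 0.01 and -0.31. Mast cell genes, highest in Ext1S100a4Cre host tumour 2, had a mean difference of 0.011 and a median of -0.025 (adjusted p = 0.98), with a direction that turned under normexp and quantile scaling.

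No list of vessel or nerve genes passed its test. Endothelial genes differed by -0.43 (21 of 24 lower, adjusted p = 0.674), and Apln, a peptide made by sprouting vessels, by -0.98 (SE 0.32, adjusted p = 0.747). Ext1S100a4Cre host tumour 1 alone stood at -1.19, against 0.07 to 0.13 in the 3 others of its group, and without it the list differed by -0.11. Pericyte and smooth muscle genes differed by -0.14 (13 of 16 lower, adjusted p = 0.707), or 0.13 without that tumour, and Schwann cell and nerve genes by -0.51 (14 of 15 lower, adjusted p = 0.703), or -0.15 without it. Without WT host tumour 3 the Schwann list differed by -0.21 and the pericyte list by 0.00. Lymphatic endothelial genes had a mean difference of -0.01 and a median of 0.09 (adjusted p = 0.98; -0.51 to 0.50 with 1 tumour left out), with a direction that turned under quantile scaling and in the series matrix.

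No list of proliferation or cell state passed its test. The cell cycle list differed by -0.034 (13 of 32 higher, adjusted p = 0.9), and its member with the smallest p, cyclin E2 (Ccne2), by -0.29, or 0.027 with normexp. Targets of p53 and apoptosis genes differed by 0.057 (15 of 22 higher, adjusted p = 0.637; for changes in either direction 0.126). Among them the cell cycle inhibitor Cdkn1a (0.46, SE 0.14), the stress gene Sesn2 (0.42, SE 0.13) and the apoptosis gene Bbc3 (0.49, SE 0.19) were higher and Pmaip1 (-0.94, SE 0.35) lower, none past the list alone (smallest adjusted p 0.147). Oxidative phosphorylation genes differed by 0.13 (27 of 29 higher, Ndufa4 0.33, adjusted p = 0.637), unfolded protein response genes by 0.045 (13 of 21 higher, Asns 0.44, adjusted p = 0.854), and FGF and ERK feedback genes by 0.064 (11 of 19 higher, adjusted p = 0.854). Hypoxia response genes differed by 0.086 (19 of 26 higher, adjusted p = 0.882), with Ddit4 at 0.93 and Angptl4 at -0.70. The directions of these 5 lists, from p53 targets to hypoxia, were reversed in the unscaled series matrix, and those of the unfolded protein response and hypoxia also under quantile scaling. Immediate early and heat shock genes differed by -0.16 (16 of 24 lower, adjusted p = 0.854). Colon-type epithelial genes differed by 0.13 (13 of 20 higher, adjusted p = 0.854), among them Cdx1, an intestinal transcription factor, at 1.92 (SE 0.61), and the series matrix reversed the list.

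Muscle, erythrocyte and adipocyte lists had higher means in the Ext1S100a4Cre host, and the skin list a lower one. Skeletal muscle genes differed by 2.20, all 22 measured members had a higher mean, and 7 had unadjusted p under 0.05, yet the list did not pass (adjusted p = 0.637). Tumours 2 and 3 of the Ext1S100a4Cre host stood at 2.98 and 3.29 relative to the mean of the 8 tumours, tumours 1 and 4 at -1.32 and -0.56, and the WT host tumours between -1.19 and -1.02. Actn3 was the member past the threshold over the list alone (adjusted p = 0.0354), and Ttn, Tnnt3 and Mb differed by 2.75, 2.73 and 4.08. Erythrocyte and platelet genes differed by 1.23 (9 of 11 higher, adjusted p = 0.637), or 0.70 without Ext1S100a4Cre host tumour 2, which stood at 2.20. The haemoglobin genes Hba-a1 and Hba-a2, 2 nearly identical genes, were 3.00-fold and 2.98-fold higher, Hbb-b1 and Hbb-bt 5.33-fold and 4.53-fold, and 0 members passed over the list alone (smallest adjusted p 0.0719). Adipocyte genes differed by 0.40 (13 of 19 higher, Cidea 1.48, adjusted p = 0.854), reversed in the series matrix and at -0.28 without Ext1S100a4Cre host tumour 3, without which the muscle list differed by 1.46. Skin keratinocyte and hair follicle genes differed by -0.11 (8 of 13 lower, adjusted p = 0.733; Krt10 0.53, Krt17 -0.82, Krt14 -0.56), with the direction reversed under normexp.

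The sex-linked list showed that the Ext1S100a4Cre host tumours were of 2 kinds. Ddx3y, Eif2s3y, Kdm5d and Uty, all on the Y chromosome, were well above background in the 4 WT host tumours and in tumours 2 and 3 of the Ext1S100a4Cre host, and not in its tumours 1 and 4. Eif2s3y measured -8.53 and -8.15 in those 2 tumours and between -2.25 and -0.40 in the other 6. The 4 tested members differed by -2.17 on average between hosts (adjusted p = 0.637). Tumours 1 and 4 also had the 2 lowest fibroblast list means of all 8 tumours (-2.73 and -0.82), and tumours 2 and 3 were those with the muscle signal.

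**Figure D4:**
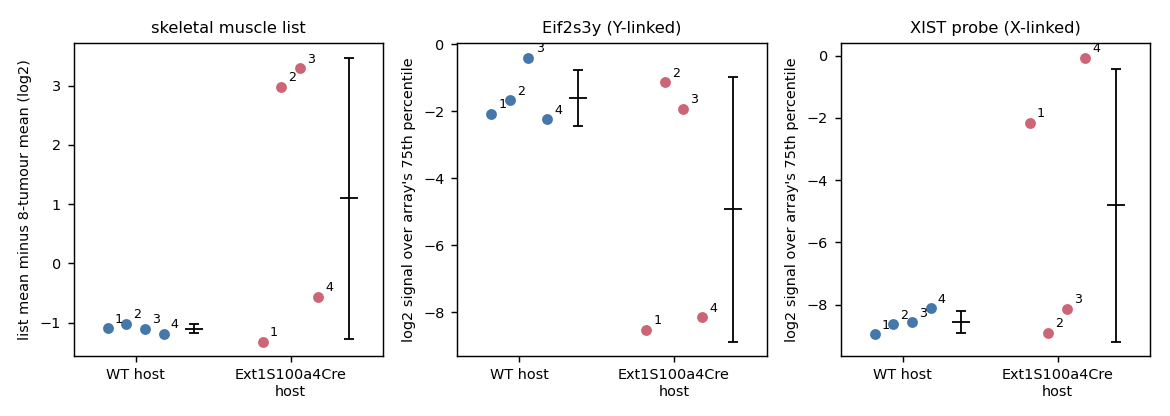
Skeletal muscle list mean, the Y-linked gene Eif2s3y and the XIST probe in each tumour, in log2 units (list mean relative to the 8 tumours, genes relative to the array's 75th percentile); points are tumours with their replicate number, and the black mark and bar give mean and SD of 4. In the Ext1S100a4Cre host, tumours 2 and 3 carry muscle and Y-linked signal, and tumours 1 and 4 carry XIST signal.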

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

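Of the tests in this part, those of host sex by the XIST probe and of muscle genes left untested were chosen before their results were seen, and those of the share of host cells and of host genotype after. Tumours 1 and 4 of the Ext1S100a4Cre host lacked Y-linked signal, and a signal that no comparison in the report uses stood beside it: the XIST probe, for an RNA made from the inactive X chromosome, was well above background in these 2 tumours alone. The lower of them exceeded the highest of the 6 others by 5.95 log2 units, and a second Xist probe did so by 0.68, which is what host animals of the other sex would give. Fewer host cells in the tumour could not give this gain of XIST, but a lower share may stand beside it in tumour 1, where the macrophage list lay 2.47 below the lowest of the 6 others and the Y-linked mean 3.86 (0.74 and 3.72 in tumour 4). The labels give no sex of the hosts, so a host sex that differs within 1 group and between the groups is a hypothesis from these data. Differences of the Ext1S100a4Cre host that rest on tumours 1 and 4 may hold an effect of sex, and a mislabelled sample was not tested.

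Skeletal muscle genes were high in tumours 2 and 3 of the Ext1S100a4Cre host. Of the 22 members tested, 20 were higher in both tumours than in all 6 others, which restates the pattern. Muscle tissue taken with the tumour is a candidate explanation: the 4 members detected in too few tumours to be tested, Ckmt2, Myh2, Myh4 and Neb, were also higher in both (4 of 4; Myh2 at 1.61 and 2.43 against at most -5.97), which does not tell such tissue from muscle genes active in the tumour. Host genotype remains open, because the list mean of tumours 1 and 4 lay 0.08 above the highest WT host tumour, with tumour 4 above the WT host range and tumour 1 below it.

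A test for a single tumour far from the 3 others of its group, applied to 124 groups of 4, singled out 5, against 6.2 by chance. The value given is the tumour's gap to its nearest neighbour over the group's range, which exceeded Dixon's 95% limit for 4 samples. In the WT host, tumour 3 was highest in the lists of chondroitin and hyaluronan synthesis (0.894), immediate early and heat shock genes (0.933) and unfolded protein response (0.903). In the Ext1S100a4Cre host, tumour 1 was lowest for endothelium (0.955) and for the gene Ttll9 (0.882).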

How the results depend on the processing

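The 2 settings that leave out a pair of Ext1S100a4Cre host tumours were chosen after the result was seen, and all other settings were planned. Limma's count of 0 genes past the adjusted threshold held with quantile and median scaling, the series matrix, both other filters, both other ways to treat probes, both blocks, a trended and robust variance and a threshold of 0.1. With normexp and with array weights it became 1, higher in the Ext1S100a4Cre host each time: the unnamed transcript ENSMUST00000188321, named after its value was seen. Leaving out 1 tumour gave 0 to 2 genes (2, both higher, without WT host tumour 3). Leaving out tumours 1 and 4 of the Ext1S100a4Cre host gave 11 genes, all 11 higher, a setting that keeps the 2 tumours with the muscle signal, and leaving out its tumours 2 and 3 gave 0. Ext1 was lower under all 21 alternatives run for it, between -0.53 and -0.14, and passed in 0.

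The count at unadjusted p under 0.05 and at least 2-fold, 462 in the report, became 156 with normexp (123 shared), 733 with no filter, 289 with the filter on all 8 arrays, 980 with the replicate block and 1768 without Ext1S100a4Cre host tumours 2 and 3. Leaving out 1 tumour gave 262 (without WT host tumour 3) to 937 (without Ext1S100a4Cre host tumour 3). The cause was not tested, apart from the number of genes tested under the filters. The median difference over all genes was 0.05 in the report's scaling, 0.102 with normexp and -0.199 in the series matrix, which carries the lower brightness of Ext1S100a4Cre host arrays 1 and 4. At unadjusted p under 0.05, 67% of genes were higher in the report's scaling, 85.2% with normexp and 6.38% in the series matrix. At 2-fold as well, 44.4% were higher against 8.94% in the series matrix (61 higher, 621 lower). The separation of the groups had an exact permutation p of 0.143 without Ext1S100a4Cre host tumour 3 to 0.543 without WT host tumour 3, where the distance turned.

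The replicate numbers did not pair the tumours throughout. Deviations of tumours with the same number correlated across genes at 0.493, -0.162, 0.591 and -0.245. The numbers 1 and 3 matched their own number best, and 2 and 4 another number, so these values do not settle whether the numbers mark pairs. With the replicate block, limma called 0 genes and fry 1 secondary list, MHC class I and II (adjusted p = 0.0172; 1.75e-09 to 0.991 over all alternatives).

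No list passed in fry in the report, and over the alternatives, camera included, list tests kept direction and side of the threshold in 772 of 863 cases. With a preset correlation of 0.01, camera called 6 primary lists: fibroblasts (8.19e-07), collagens (1.56e-10), endothelium (7.26e-06), T and NK cells (9.19e-06), macrophages (1.33e-09) and interferon response (2.33e-05). It also called 15 secondary lists. With an estimated correlation it called none of these, with a smallest adjusted p of 0.492. Both camera runs turned the epithelial list (0.957 preset, 0.983 estimated) and the lymphatic list (0.833 and 0.983). Without Ext1S100a4Cre host tumours 1 and 4, fry called 1 secondary list, skeletal muscle, which tells nothing new, as the 2 tumours kept are those with its signal.

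Other lists changed direction without passing, mostly from differences near 0, with the adjusted p given here and the cause not tested. With normexp these were heparan sulfate (0.938), hedgehog (0.846), mast cell (0.893) and keratinocyte genes (0.927). With quantile scaling these were mast cell and hypoxia genes (0.995 each), unfolded protein response (0.981) and lymphatic genes (0.909). The series matrix turned FGF and ERK feedback (0.593), hypoxia (0.67), oxidative phosphorylation (0.375), unfolded protein response (0.305), p53 (0.512), epithelial (0.651), adipocyte (0.865) and lymphatic genes (0.659). Mast cell genes turned with no filter (0.875), every probe (0.985) and array weights (0.915). Lymphatic genes turned with the filter on all 8 arrays (0.992), and hedgehog genes with the replicate block (0.947). FGF and ERK feedback and immediate early genes turned with array weights (0.848 each).

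Without Ext1S100a4Cre host tumours 1 and 4, the lists of interferon response, proteoglycans, Wnt, hedgehog, pericytes, mast cells, hypoxia, oxidative phosphorylation, unfolded protein response, Schwann cells and sex-linked genes turned, each at 0.991. The Y-linked genes Eif2s3y, Ddx3y and Uty then differed by 0.067, 0.295 and 0.422. Without tumours 2 and 3, cell cycle (0.391), immediate early (0.934), epithelial (0.667), keratinocyte (0.722), adipocyte (0.505) and lymphatic genes (0.324) turned. S100a4 turned to -0.138 in the series matrix and -0.534 without tumours 2 and 3, and without 1 tumour ranged from -0.194 to 0.645. Trim42 (0.052) and Ccne2 (0.027) turned with normexp, which compresses low signals.

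Leaving out 1 tumour turned fry's direction for 13 lists at least once. Fry's adjusted p ran from 0.703 to 0.984 for cell cycle, 0.7 to 0.963 for FGF and ERK feedback and 0.476 to 0.963 for Wnt. It was 0.435 to 0.964 for hedgehog, 0.656 to 0.914 for neutrophils and 0.703 to 0.967 for mast cells. For hypoxia and for unfolded protein response it was 0.703 to 0.998, and for immediate early genes 0.703 to 0.964. Epithelium had 0.624 to 0.971, keratinocytes 0.656 to 0.963, adipocytes 0.756 to 0.967 and lymphatic genes 0.703 to 0.967. The list means of pericytes (0.13) and chemokines (0.01) also turned without Ext1S100a4Cre host tumour 1, though fry's direction did not. Of Ms4a1, Cd79b and Fcmr, 2 to 3 passed over the B-cell list alone when 1 tumour was left out and 0 with normexp. Signal over background limits this: Ms4a1, Fcrl1 and Klrh1 have only bounds in the Ext1S100a4Cre host.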

Other observations

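All tests of chromosome 6 in this part were chosen after its shift was seen, except that by correlation with the fibroblast list. The result of that test was unseen when it was chosen. The counts of splits for the 2 gene counts were planned.

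Genes of chromosome 6 were slightly higher in each Ext1S100a4Cre host tumour than in any WT host tumour. The median of its 892 named genes, relative to all named genes, differed by 0.116, with WT host tumours from -0.106 to -0.037 and Ext1S100a4Cre host tumours from 0.026 to 0.072 (exact permutation p = 0.0286, the smallest possible; adjusted over 20 chromosomes 0.19). The next largest chromosome difference was -0.054, on chromosome 14. Chromosomes 14 and 16 (-0.03) also did not overlap between the groups and had the same exact permutation p and adjusted p, so these are not particular to chromosome 6. In bins of 25 neighbouring genes, 26 of 35 bins of chromosome 6 were higher (74.3%), against 327 of 642 elsewhere (50.9%). In the upper part of named genes by mean signal (419 on chromosome 6) the difference was 0.177 (adjusted p = 0.229).

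A copy-number difference between the transplanted cells is a candidate explanation. Its genes were grouped by signed correlation with the fibroblast list within groups. In the 297 with the lowest correlation, where inverse ones fall, the difference was 0.211. In the middle 275 genes it was 0.107 (exact permutation p = 0.0286 for both), and in the 320 with the highest correlation -0.004. Genes with a correlation near 0 were not set apart. Adjustment for the fibroblast list left it in place, at 0.122 (SE 0.024) with that list in the fit and 0.116 (SE 0.019) without. Shares of other host cells were not adjusted for, so the share of host cells as a whole was not tested. Host sex also left it in place, at 0.126 among the 6 tumours with Y-linked signal. Of the 35 splits of the tumours only the real one, 1 split, gave some chromosome a difference as large as 0.116 (highest other 0.085), the smallest share that 35 splits allow, in a test prompted by this value; an effect of the host's genotype through other routes, and why the cells of 2 groups would differ, were not tested.

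For genes past the threshold the splits say nothing about chance: the real count was 0, which all 35 of 35 splits reach by construction, and the highest other count was 100. The split with that count set WT host tumours 1 and 2 with Ext1S100a4Cre host tumours 1 and 4 against the rest. These are the tumours with negative values on the first principal component (-25.6, -3.8, -122 and -52.5). The split was picked for its count, and a structure of the samples other than host genotype was not tested. For genes at unadjusted p under 0.05 and at least 2-fold chance was not excluded: 11 of 35 splits gave as many as the real 462, and that same split gave the most, 1787.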
